A study of Caenorhabditis elegans with 4 samples.

How the data were processed

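Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for the transcription factors UNC-30 and UNC-55 of the nematode Caenorhabditis elegans. Per the labels' protocols, whole L2 larvae kept at 22 or 25 °C on plates with the OP50 bacterial food were lysed, and DNA was isolated with beads that bind GFP. The series holds 4 samples: 1 ChIP sample per factor and 1 input sample per factor, taken without antibody. The labels give the same strain name, GSH100, for all of them, so the tagged factor in each sample is known here only from the sample titles.

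The authors deposited 1 peak list per ChIP sample, and each list gives the chromosome, the start and the end of a peak and nothing else. The lists hold no peak height, fold enrichment, score, p-value or gene name. The aligner, the peak caller, its threshold, the use made of the input and the genome build are not given in the sources used here. Read depth is unknown for the same reason. No values of the input samples were analysed here. Every start is a multiple of 50 and every end lies 49 past such a multiple, and 1 peak on X starts at 0. The deposited positions therefore count from 0 with the end included, and the peaks are runs of 50 bp bins. Coordinates below were converted to count from 1. The 50 bp grid sets the resolution of every width and position.

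Because no build is named, the only gene table at hand (assembly WBcel235, without strand) was compared with the peaks before any use. Of the UNC-30 peaks, 49 had their centre within 300 bp of the midpoint of a tRNA gene in that table, against a mean of 10.9 and a maximum of 20 in 100 draws in which the peaks were moved by 2000 to 10000 bp. Of the UNC-55 peaks, 10 did, against a mean of 9.72. The 49 UNC-30 peaks were not centred on the tRNA genes. Their centres lay at lower coordinates in 46 cases, by a median offset of -113.5 bp, and the median offset ran from -71.0 bp on chromosome IV to -186.0 bp on V, where only 2 peaks entered. The coordinates thus lie near those of WBcel235, but the build was not settled, and no peak was assigned to a gene. The planned results on promoters, target genes, gene lists and sequence motifs were not run, since they need an annotation or a sequence of the build used. The planned ranking by caller value was replaced by peak width, the only property of a peak in the lists.

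Peaks of the lists were called shared when they overlapped by at least 1 bp. The count of shared peaks was set beside 10000 random placements of the UNC-55 peaks on their own chromosome, with widths and the 50 bp grid kept. A second placement moved each UNC-55 peak by 2000 to 10000 bp to a random side, which keeps the regional density. For shares by peak width, for the distance between unshared peaks and for the grouping of peaks within a list, the peaks of each list were moved in the same way 1000 times. Chromosome length was taken as the span from the first position to the last peak end in either list. Shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent. There is 1 library per factor, so no difference between the factors has a replicate check, and no p-value is given. The placements describe these lists and are not a test across animals.

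The rule for named items was fixed before the data were examined and asked for genes ranked by caller value. Since neither was at hand, the items named are regions chosen after the lists were seen: the 10 widest peaks per list, the 10 shared pairs with the best sum of width ranks, and the regions holding most peaks when peaks under 2000 bp apart are joined. Alternatives fixed before the data were examined were an overlap of at least 50% of either peak and centres within 200 bp. Those added afterwards were the moved placement, peaks of at least 300 bp only, joining of peaks under 500 bp apart, leaving out X, and leaving out peaks wider than 2000 bp. The overlap count was tested on simulated data: lists of 2609 peaks with 30% or 60% set on UNC-30 peaks and the others kept off them gave 30.0% and 60.0%, which checks the counting and not chance overlap. The random placement was checked against an exact value: the mean count of UNC-55 peaks meeting a UNC-30 peak over 1000 placements was 43.28 (standard error 0.209), and the exact expectation, enumerated over every start on the grid, was 43.34. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.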

Results

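To compare where UNC-30 and UNC-55 bind in the worm genome, peak lists of both factors from whole L2 larvae were examined. UNC-30 is a Pitx-type homeodomain factor required for the identity of the D-type GABA motor neurons. UNC-55 is a nuclear receptor of the COUP-TF family that acts in the VD class of these neurons. The UNC-30 list held 2875 peaks and the UNC-55 list 2609, each from 1 library, so the differences between factors below have no replicate check. UNC-30 peaks had a median width of 300 bp (quartiles 200 and 450 bp), and UNC-55 peaks one of 250 bp (quartiles 150 and 350 bp). The UNC-30 peaks covered 971.0 kb in all and the UNC-55 peaks 683 kb, a ratio of 1.42. The mapped depth of either library is unknown, and the number and width of peaks also follow from depth and from the caller's threshold. Positions are those of the deposited lists, counted from 1, whose genome build is not given in the sources used here.

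Both factors had their highest peak density on the X chromosome. X carried 709 UNC-30 peaks (24.7% of the list, 95% exact binomial interval 23.1 to 26.3%) and 671 UNC-55 peaks (25.7%, interval 24.1 to 27.4%), while it made up 17.6% of the spanned length. This corresponded to 40.2 UNC-30 and 38.1 UNC-55 peaks per Mb on X, against 26.3 and 23.5 per Mb over the 5 autosomes. Relative to its length, X held 1.40 times the expected UNC-30 peaks (interval 1.31 to 1.49) and 1.46 times the expected UNC-55 peaks (interval 1.36 to 1.56). Chromosome V was the sparsest for both factors, with 20.3 UNC-30 and 19.2 UNC-55 peaks per Mb, or 0.705 and 0.737 times the expected number. Chromosome IV was also below its length share for both factors, at 0.823 and 0.816 times. Chromosome III held 1.13 times the expected UNC-30 peaks (interval 1.03 to 1.23) and 0.990 times the expected UNC-55 peaks (interval 0.896 to 1.09), and these intervals overlap. The X shares of the factors differed by less than their intervals. Shared sites count in both lists, as for 241 UNC-30 and 242 UNC-55 peaks on III. Overlap of the intervals therefore does not rule out a difference between the factors.

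On the autosomes the peaks of both factors were denser in the middle of the chromosome than in its outer parts. The central part, of 3 parts of equal length per chromosome, held 41.8% of autosomal UNC-30 peaks (interval 39.7 to 43.9%, 906 of 2166) and 44.5% of autosomal UNC-55 peaks (interval 42.3 to 46.8%, 863 of 1938). The central share was highest on V, at 47.4% for UNC-30 and 49.8% for UNC-55. Among the autosomes it was lowest on III for UNC-30, at 37.9% (interval 33.4 to 42.6%), where the right part held 33.6%. For UNC-55 it was lowest on IV, at 40.2% (interval 35.1 to 45.3%). Over the same 3 parts of X the shares were nearly even, with 31.7% of UNC-30 peaks (interval 28.3 to 35.3%) and 34.9% of UNC-55 peaks (interval 31.3 to 38.6%) in the central part. In the 97 complete windows of 1 Mb, the number of UNC-30 peaks ranged from 5 to 67 with a median of 27, and the number of UNC-55 peaks from 4 to 61 with a median of 26. The fullest window for both factors was X 4000001 to 5000000, with 67 UNC-30 and 61 UNC-55 peaks. Next came I 9000001 to 10000000 for UNC-30, with 55 peaks, and II 6000001 to 7000000 for UNC-55, with 54 peaks. The windows V 16000001 to 17000000 and V 18000001 to 19000000 each held 6 UNC-30 and 5 UNC-55 peaks. The widest gap in favour of UNC-30 was at III 5000001 to 6000000, with 45 UNC-30 and 29 UNC-55 peaks. A difference of 15 peaks in the same direction was found at II 12000001 to 13000000 (31 and 16), III 10000001 to 11000000 (40 and 25) and III 11000001 to 12000000 (29 and 14). The widest gap in favour of UNC-55 was at II 9000001 to 10000000, with 36 UNC-55 and 26 UNC-30 peaks. UNC-30 had more peaks in 67 windows, UNC-55 in 28, and 2 were equal. The counts were not scaled for the longer UNC-30 list (2875 against 2609 peaks). The windows named are the extremes of 97, and their differences were not tested against counting error.

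**Figure D1:**
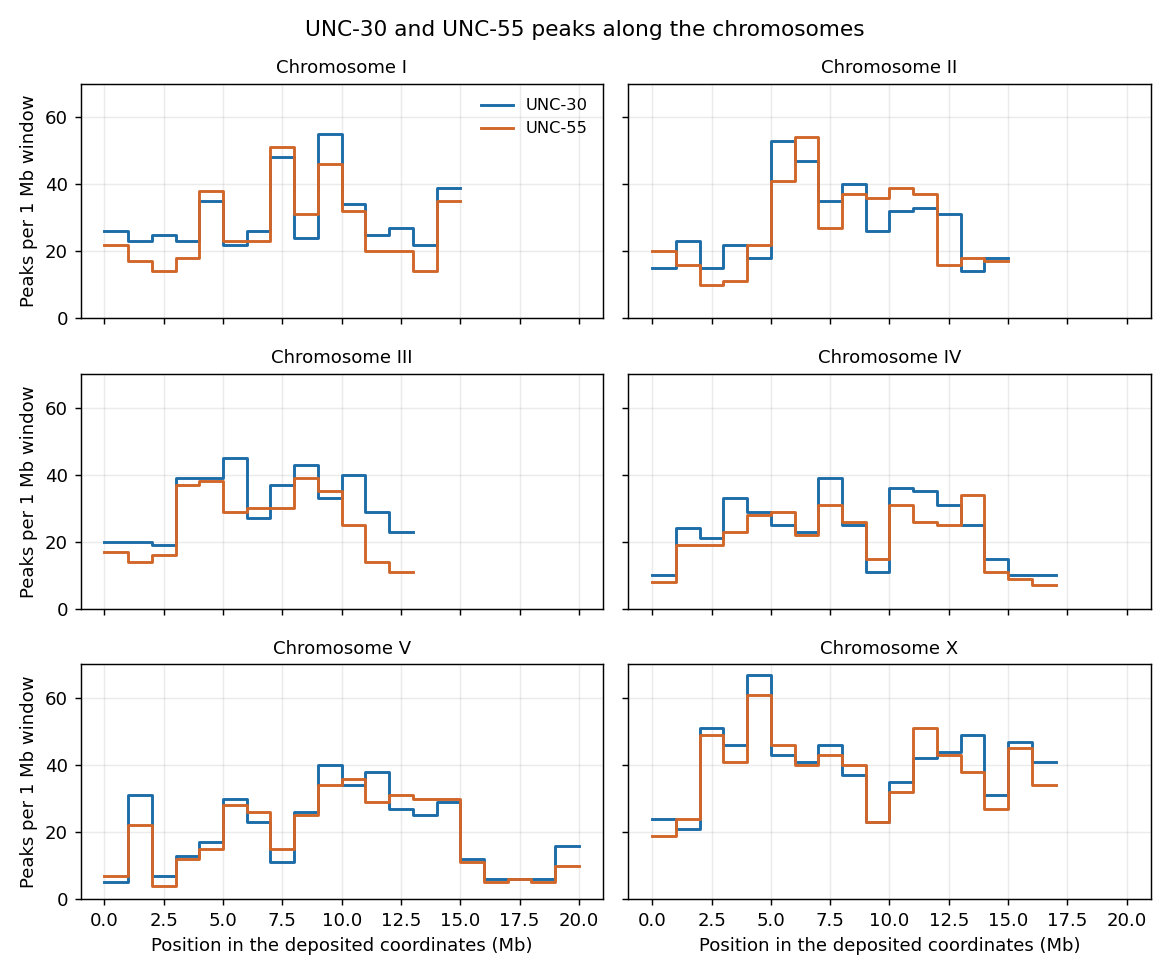
Number of peaks per complete 1 Mb window (vertical axis) along each of the 6 chromosomes (horizontal axis, Mb in the deposited coordinates), with 1 line per factor and 1 library per line. Both lines reach their highest value on X between 4 and 5 Mb, with 67 UNC-30 and 61 UNC-55 peaks. On V they are low between 16 and 19 Mb, with at most 6 peaks of either factor per window, and rise again at 19 to 20 Mb.

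In the full lists, a majority of the peaks of each factor overlapped a peak of the other. Of the UNC-30 peaks, 1589 (55.3%, interval 53.4 to 57.1%) met a UNC-55 peak, and of the UNC-55 peaks, 1607 (61.6%, interval 59.7 to 63.5%) met a UNC-30 peak. This left 1286 peaks in the UNC-30 list alone and 1002 in the UNC-55 list alone. With the UNC-55 peaks placed at random on their chromosomes, a median of 43 UNC-55 peaks met a UNC-30 peak and none of the 10000 placements exceeded 73. With each UNC-55 peak moved by 2000 to 10000 bp, the median was 90.5 and the highest count 122. The observed number was 37.4 times the median of the random placements and 17.8 times that of the moved peaks. The majority did not hold for UNC-30 when only peaks of at least 300 bp were kept in both lists: 41.8% of these UNC-30 peaks (interval 39.4 to 44.2%, 683 of 1635) and 70.9% of these UNC-55 peaks (688 of 970) were then shared. Against the full other list, 72.5% of the same UNC-30 peaks (1185 of 1635) and 79.8% of the same UNC-55 peaks (774 of 970) were shared. The lower UNC-30 share thus came from removing narrow UNC-55 partners. The shared sequence amounted to 423 kb, which is 43.5% of the length of the UNC-30 peaks and 61.9% of that of the UNC-55 peaks.

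The share of UNC-55 peaks that met a UNC-30 peak varied between chromosomes. It was 68.2% on III (interval 63 to 73%), 66.8% on IV (interval 61.8 to 71.6%) and 63.7% on I (interval 58.8 to 68.4%). It was 55.8% on II (interval 50.8 to 60.7%) and 58% on V (interval 53.0 to 62.8%). This share also depends on how many peaks each list holds on a chromosome. The UNC-30 and UNC-55 lists held 446 and 355 peaks on III and 412 and 371 on IV. They held 455 and 405 on I, 429 and 405 on II and 424 and 402 on V. The shares were not corrected for this. The share of UNC-30 peaks that met a UNC-55 peak ran from 51.7% on II (interval 46.9 to 56.6%) to 59.0% on IV (interval 54.1 to 63.8%), with overlapping intervals. On X the shares were 55.7% for UNC-30 and 59.6% for UNC-55, near those of the autosomes (55.1% and 62.3%).

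Shared peaks lay nearly on top of each other. In the 1565 pairs in which 1 peak of each list met only the other, the median distance between centres was 25.0 bp, which is below the 50 bp grid. The centres were within 50 bp in 1169 pairs (74.7%) and within 100 bp in 1459 (93.2%). The pairs were chosen for overlapping, which limits how far apart their centres can be. Pairs that overlap by chance were not compared. The UNC-55 centre lay at the higher coordinate in 616 pairs and at the lower in 630, so neither side was preferred in genome coordinates. No strand was used, so an offset relative to genes or binding sites could not be seen. The UNC-55 peak was the narrower of the pair in 1114 cases (71.2%) and the wider in 278. The median widths in these pairs were 400 bp for UNC-30 and 250 bp for UNC-55. The UNC-55 peak lay wholly within the UNC-30 peak in 1093 pairs, and the UNC-30 peak within the UNC-55 peak in 266. Both counts include the 76 pairs with identical boundaries.

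Wider peaks were shared more often in both lists. Of the UNC-30 peaks 100 to 150 bp wide, 25.8% met a UNC-55 peak (interval 22.3 to 29.5%, 149 of 578). This share was 59.4% for peaks of 300 to 400 bp and 89.6% (interval 84.5 to 93.4%, 181 of 202) for those of 650 bp or more. Of the UNC-55 peaks 100 to 150 bp wide, 42.5% met a UNC-30 peak (interval 39 to 46.1%, 328 of 772), and 90.9% did so at 450 to 600 bp (interval 86.3 to 94.4%, 200 of 220), while the 49 UNC-55 peaks of 650 bp or more had a share of 87.8% (interval 75.2 to 95.4%). The moved peaks met the other list in 1.64% of the narrowest and 6.98% of the widest UNC-30 class. Shared UNC-30 peaks had a median width of 400 bp and unshared ones 200 bp, and none of 10000 random relabellings of the peaks gave this difference of 200 bp. For UNC-55 the medians were 250 and 200 bp, a difference of 1 grid step that 155 of 10000 relabellings also gave. The mean widths, which the grid limits less, were 293 bp for shared and 211 bp for unshared UNC-55 peaks, and 409.8 and 249 bp for UNC-30.

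**Figure D2:**
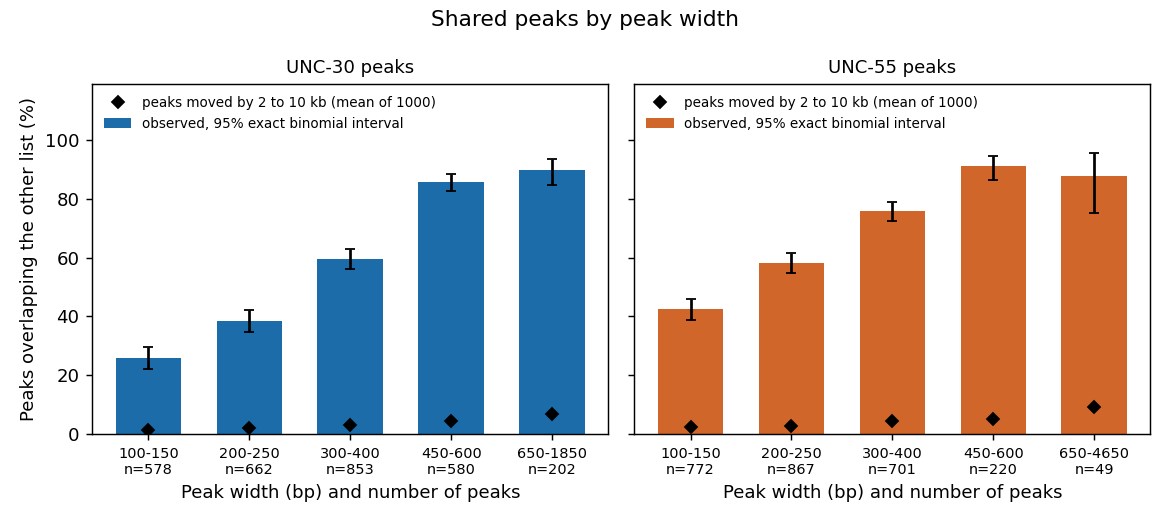
Share of peaks that overlap a peak of the other list (vertical axis, percent) by peak width (horizontal axis, bp, with the number of peaks per class), for UNC-30 on the left and UNC-55 on the right. Bars give the observed share with its 95% exact binomial interval, and diamonds the mean share over 1000 draws of the same peaks moved by 2000 to 10000 bp; for UNC-30 the bars rise from 25.8% to 89.6% while the diamonds stay at or below 6.98%.

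Among the widest peaks held in common, the pair with the best sum of width ranks lay on X, where a UNC-30 peak at 5728651 to 5729950 (1300 bp) enclosed a UNC-55 peak at 5728701 to 5729900 (1200 bp). On IV, a UNC-30 peak at 10341601 to 10342700 (1100 bp) enclosed a UNC-55 peak at 10341701 to 10342600 (900 bp). On X, a UNC-30 peak at 11605351 to 11606500 enclosed a UNC-55 peak of 800 bp, and on I, a UNC-30 peak at 9380951 to 9382000 enclosed one of 850 bp. Others of the 10 highest ranked pairs had their UNC-30 peaks at I 5315851 to 5316800, III 8416951 to 8417900, X 4740451 to 4741400, V 11340951 to 11341950, IV 7453051 to 7453950 and II 11749201 to 11750100. In each of these the overlap was at least 750 bp.

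Some of the widest peaks belonged to 1 list alone. The widest UNC-55 peak, at X 5907751 to 5912400, was 4650 bp long, and the nearest UNC-30 peak was 39650 bp away. The next, at IV 7698201 to 7700950 (2750 bp), shared 350 bp with a UNC-30 peak. These were the only 2 UNC-55 peaks wider than 2000 bp. No read or input values were used to check them, so their width cannot be read as binding. No UNC-30 peak overlapped the UNC-55 peaks at I 4124851 to 4126050 (1200 bp), V 9768801 to 9769700 (900 bp) and I 14855351 to 14856200 (850 bp). The widest UNC-30 peak, at X 4980751 to 4982600 (1850 bp), shared 1050 bp with 2 UNC-55 peaks. The UNC-30 peak at I 3391551 to 3393000 (1450 bp) was the only 1 of the 10 widest in that list with no UNC-55 peak, the nearest being 56900 bp away. Of all peaks of at least 650 bp, 21 of 202 UNC-30 peaks and 6 of 49 UNC-55 peaks were unshared.

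Peaks of both factors also gathered into groups. A peak of the same list lay under 2000 bp away for 37% of UNC-30 peaks (interval 35.2 to 38.8%) and 29.6% of UNC-55 peaks (interval 27.8 to 31.3%), against medians of 13% and 11.6% in 1000 random placements on the chromosomes. With each peak moved by 2000 to 10000 bp, which keeps the regional density, the medians were 24.4% and 21.5% and the highest shares 27.8% and 24.6%, so the observed shares were 1.51 and 1.38 times the moved medians. Joining all peaks under 2000 bp apart gave 2923 regions, of which 1426 held peaks of both factors, 809 of UNC-30 alone and 688 of UNC-55 alone. Counted over both lists, so that a shared site gives 2 peaks and regions of both factors rank higher, the fullest was II 6823101 to 6832250, with 7 UNC-30 and 6 UNC-55 peaks. It was followed by III 6133201 to 6141700, with 5 UNC-30 and 7 UNC-55 peaks, II 12657551 to 12665250, with 6 and 4, III 3618551 to 3622950, with 5 and 5, and IV 4574201 to 4581400, with 4 and 6. Regions of 1 factor alone held at most 4 peaks, at X 14775051 to 14778350, where all 4 were UNC-55 peaks.

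**Figure D3:**
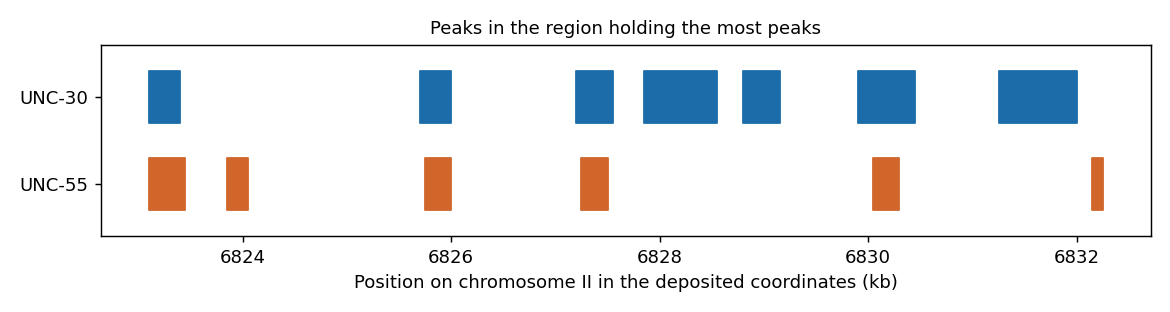
Map of the peaks in the region II 6823101 to 6832250 (horizontal axis, kb in the deposited coordinates), drawn to scale with UNC-30 peaks in the upper row and UNC-55 peaks in the lower row. Of the 7 UNC-30 peaks, those at 6827851 to 6828550, 6828801 to 6829150 and 6831251 to 6832000 have no UNC-55 peak over them.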

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

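Of 23 alternative values, 16 lay within the 95% interval of the main value or, for the ratio of covered lengths (1.44 without peaks wider than 2000 bp), close to it. An overlap of at least 50% of either peak, centres within 200 bp, joining of peaks under 500 bp apart and leaving out X kept the shared part between 54.5 and 56.7% of UNC-30 peaks and between 60.2 and 62.3% of UNC-55 peaks. With only peaks of at least 300 bp in both lists, 41.8% of UNC-30 peaks were shared, no longer a majority, and 70.9% of UNC-55 peaks. Against the full other list, 72.5% of UNC-30 and 79.8% of UNC-55 peaks of that width were shared, so choosing wide peaks raised the share and removing narrow partners lowered it. The same restriction put 27.8% of UNC-55 peaks on X (interval 25.0 to 30.8%). Against peaks moved by 2000 to 10000 bp in place of random placement, the excess of shared peaks was 17.9 times for UNC-30, where random placement gave 37 times, and 17.8 times for UNC-55. The excess of peaks with a neighbour of their own list under 2000 bp away was 1.51 times for UNC-30 and 1.38 times for UNC-55 against moved peaks, and 2.83 and 2.55 times against random placement. The placement by distance to transcript starts, the stricter lists by caller value and the alternatives for promoters, genes, gene lists, motifs and summits were not run, because the lists hold no caller value, summit or named build. No paired analysis was possible because each factor has 1 library, so no replicate could be left out either. Without read counts or input values, a peak missing from 1 list cannot be read as absent binding.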

Other observations

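The counts by region and by distance below were chosen after the lists were seen. The predictions for the explanations weighed were written before the results of their tests were seen. The overlap itself and its rise with peak width were already known by then. Unshared peaks lay under 2000 bp from a peak of the other factor more often than moved peaks did, though most lay farther away. Of the unshared UNC-30 peaks, 29.9% (interval 27.4 to 32.5%, 385 of 1286) had a UNC-55 peak less than 2000 bp away. When the same peaks were moved by 2000 to 10000 bp and those that then overlapped were left out, the mean share over 1000 draws was 16.4% and the highest 19.2%. Of the unshared UNC-55 peaks, 25.3% (interval 22.7 to 28.2%, 254 of 1002) had a UNC-30 peak less than 2000 bp away, against a mean of 15.6% and a highest share of 18.7% for the moved peaks. Moves of this size also take peaks out of the groups of their own list, some of which hold shared peaks. The excess therefore cannot be told apart from the grouping within each list. At less than 500 bp the shares were 6.92% for UNC-30 (highest moved share 6.84%) and 5.19% for UNC-55 (highest moved share 6.92%), so the UNC-55 value lay within the range of the moved peaks. The median gap to the other list was 6800 bp for unshared UNC-30 peaks and 8425 bp for unshared UNC-55 peaks. With peaks under 2000 bp apart joined, 5 regions held 3 peaks of UNC-30 alone, at X 2456051 to 2459850, III 5685101 to 5688450, V 6244401 to 6247600, V 9191351 to 9193250 and V 20706051 to 20708650. The 6 regions with 3 peaks of UNC-55 alone were X 4236151 to 4239300, X 4574101 to 4576500, X 7232401 to 7235100, X 11744451 to 11747250, V 9765651 to 9769700 and IV 13218401 to 13220800. Of these regions, 1 of the 5 and 4 of the 6 were on X. X held 24.7% of all UNC-30 and 25.7% of all UNC-55 peaks, at a higher density than the autosomes. The regions are few, and their placement on X was not tested.

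In the full lists a majority of the peaks of each factor overlapped a peak of the other. This did not hold for UNC-30 with peaks of at least 300 bp only in both lists (41.8%). Of the same UNC-30 peaks, 72.5% met a peak of the full UNC-55 list. If both lists only crowded into the same wider regions, UNC-55 peaks moved by 2000 to 10000 bp would meet UNC-30 peaks about as often. The highest of 10000 such placements gave 122 shared UNC-55 peaks against 1607 observed. Crowding alone is thus argued against for regions wider than these moves. Crowding on a finer scale was not tested, because the moves also take peaks out of their groups. Regions that give peaks in any such ChIP of these worms stay open: the number of control peak lists in which the shared peaks could be looked up was 0. The same holds for binding of both factors at the same sites, in the same or in different cells, which was not tested. Data from whole animals of 1 strain label and a common GFP pulldown cannot separate these possibilities. The tagged factor of each sample is known only from its title, so the overlap also rests on those titles.

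Wider peaks were shared more often. Chance encounters of wider peaks may add to this but are too few: after subtracting the share of moved peaks, the widest UNC-30 class exceeded the narrowest by 58.5 percentage points (joint error 6.31), and the widest UNC-55 class by 38.3 points (joint error 13). A partner close by that does not touch the narrow peak is argued against as well, since counting partners within 500 bp left differences of 52.6 points for UNC-30 and 33.6 points for UNC-55. Whether narrow peaks lie nearer to the caller's threshold, and so are missed more often in the other list, stays untested, because the lists give no height.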
